A study of Bos taurus with 8 samples.

How the data were processed

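The series held 8 two-colour arrays of bovine 2-cell embryos, each hybridised with RNA from embryos collected at 29.5 hpf and at 46 hpf, as 4 labelled replicates with exchanged dyes. Per the labels' protocols, oocytes were matured and fertilized in vitro with pooled semen, RNA was amplified by rounds of T7 transcription, and Cy3 and Cy5 were attached chemically. Whether each replicate was a separate pool of embryos rests on the series' own statement that the replicates were biological. The scanner files give linear intensity values per the file headers, the mean spot signal and median local background at 532 nm for Cy3 and 635 nm for Cy5, not normalized. The series' value table holds log2 ratios made by the authors, whose normalization is not given in the sources used here. Set against the scanner values over the brighter probes, each of its columns had a slope near 1 in size (0.96 to 1.12 where 29.5 hpf was in Cy5 and -1.18 to -1.02 where 46 hpf was), so its columns already ran as 29.5 hpf over 46 hpf. Its column medians were between -0.0151 and 0.0120. It was used as an alternative only, for its 43776 probes.

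Each array held 45212 spots with an identifier, of which 1418 were controls and 43794 were probes with 1 spot each. Background was corrected by normexp with an offset of 50, and log ratios were normalized within each array by loess, with control spots and the 28 to 186 spots per array that the image software left out at weight 0, and without scaling between arrays (limma 3.58.1, R 4.3.3). The sign of arrays with 46 hpf in Cy5 was turned, and the dye-swapped arrays of 1 replicate number were averaged. A probe was tested when its signal was above the mean plus 2 SD of the 153 negative control spots of that array and channel on at least 4 of the 8 arrays in the channels of 1 group, and when at least 3 replicates had a value. The mean of the 4 replicate values was tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over 32987 probes and a threshold of 0.05. The spread of p-values is that between the 4 labelled replicates.

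Probes were named from the platform annotation, in which 21781 probes had 1 symbol, 0 had several and 22013 of the array's probes had none listed. Symbols were updated through the RefSeq gene table of assembly ARS-UCD2.0, where 20036 probes had a current symbol, 1524 were renamed through a synonym and 221 were kept as given. No coordinates were used, because the probes' build is not given in the sources used here. A gene was represented by its tested probe with the highest mean intensity. The 25 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Genes named in the text were the 12 largest rises and 12 largest falls among genes past the threshold with 1 sign in all 4 replicates, and up to 4 members of each list with the smallest p; LOC symbols were counted (5 called genes) and not named. Other probes of called named genes are given where they differ; for members not past the threshold, mostly the brightest probe alone is given. Settings, lists and this rule were chosen before the data were examined, unless stated.

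The numbering was checked by correlating the arrays. Deviations from the mean of all arrays correlated at -0.28 and -0.19 between the arrays numbered 1 and between those numbered 2, and at 0.29 and 0.50 for numbers 3 and 4, so the labelled numbers did not pair all arrays. The labelled averaging was kept as the main setting, since it had been fixed, and the exchanged numbering was added as an alternative. On simulated data with the real spread (32473 probes, 200 changed, 10 runs), 68.3% of 2-fold and 91.4% of 3-fold changes were recovered, with 5.9 false calls per run. In these runs the labelled numbers were the true pairs by construction, with a correlation within a pair of 0.484 taken from the exchanged numbering. The rates thus hold for correctly paired arrays and were not obtained for wrong pairs. In 50 runs with no change, 5.43% of probes had p under 0.05 when arrays were averaged in their true pairs and 8.23% when averaged in wrong pairs, and neither gave a call after adjustment. In 20 simulated list tests a shift of 0.5 was called in 20 and a flat list in 1. These calls were at an unadjusted p under 0.05 by limma camera, in lists of 40 independently drawn genes. The shift was larger than the median of any list reported below, so recovery at those sizes was not examined. Alternatives covered background correction, normalization, the filter, the authors' values, pairing and blocks, dye orientation, the variance model, array weights, left-out replicates, the fold threshold and the list tests.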

Results

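Messenger RNA of bovine 2-cell embryos produced in vitro was compared between embryos collected at 29.5 hours post-fertilization (hpf), called fast in the labels, and embryos collected at 46 hpf, called slow. The question, as the series states it, was how the transcripts of embryos that cleave early differ from those of embryos that cleave late. Amplified RNA of both groups was hybridised together on 8 two-colour oligonucleotide arrays of the EmbryoGENE type. On 4 arrays the 29.5 hpf RNA carried Cy5, and on the other 4 the dyes were exchanged. The labels number the arrays as 4 biological replicates, each measured on a pair of dye-swapped arrays. The number of embryos in each sample was not given in the sources used here. All ratios below are log2 of 29.5 hpf over 46 hpf, so a positive value means more signal in the embryos collected at 29.5 hpf. Time of collection and speed of cleavage changed together in this design, so a difference belongs to both. The arrays held 43794 probes, of which 32987 were above background often enough to be tested. The number of arrays limits the precision, and the median raw signal over probes was between 152.1 and 343.8 in Cy5 and between 128.5 and 195.7 in Cy3.

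With the arrays averaged by their labelled number, 208 probes were higher and 174 were lower at 29.5 hpf (limma, adjusted p under 0.05). Among the genes with the largest rises were APC, a scaffold of the complex that degrades beta-catenin, with a log2 ratio of 1.63 ± 0.51 (SD, n = 4), and ANKLE2, a protein of nuclear envelope reassembly, with 1.56 ± 0.54 (SD, n = 4). HNRNPH1, an RNA-binding splicing regulator, was higher by 1.51 ± 0.03 (SD, n = 4), and SMAD1, a transducer of BMP signals, by 1.36 ± 0.11 (SD, n = 4). CKAP5, a microtubule polymerase of the spindle, was higher by 1.45 ± 0.36 (SD, n = 4), and RRM1, the large subunit of ribonucleotide reductase, by 1.35 ± 0.24 (SD, n = 4). HERC2, ESPL1, GPN2, TBC1D15, WDR19 and DHTKD1 completed the 12 largest rises, with log2 ratios from 1.36 for HERC2 down to 1.29 for DHTKD1. The largest falls were those of ARPC5, a subunit of the actin-nucleating Arp2/3 complex, at -1.37 ± 0.30 (SD, n = 4), and MAL2, a membrane trafficking protein, at -1.35 ± 0.20 (SD, n = 4). SERPINE2, a secreted protease inhibitor, was at -1.28 ± 0.10 (SD, n = 4), and AURKB, the kinase of the chromosomal passenger complex, at -1.09 ± 0.18 (SD, n = 4). HOOK3, SYF2, CELF1, UPF3B, KIF3C, HNRNPDL, CHAMP1 and KPNA3 followed, from -1.08 for HOOK3 to -0.92 for KPNA3.

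**Figure D1:**
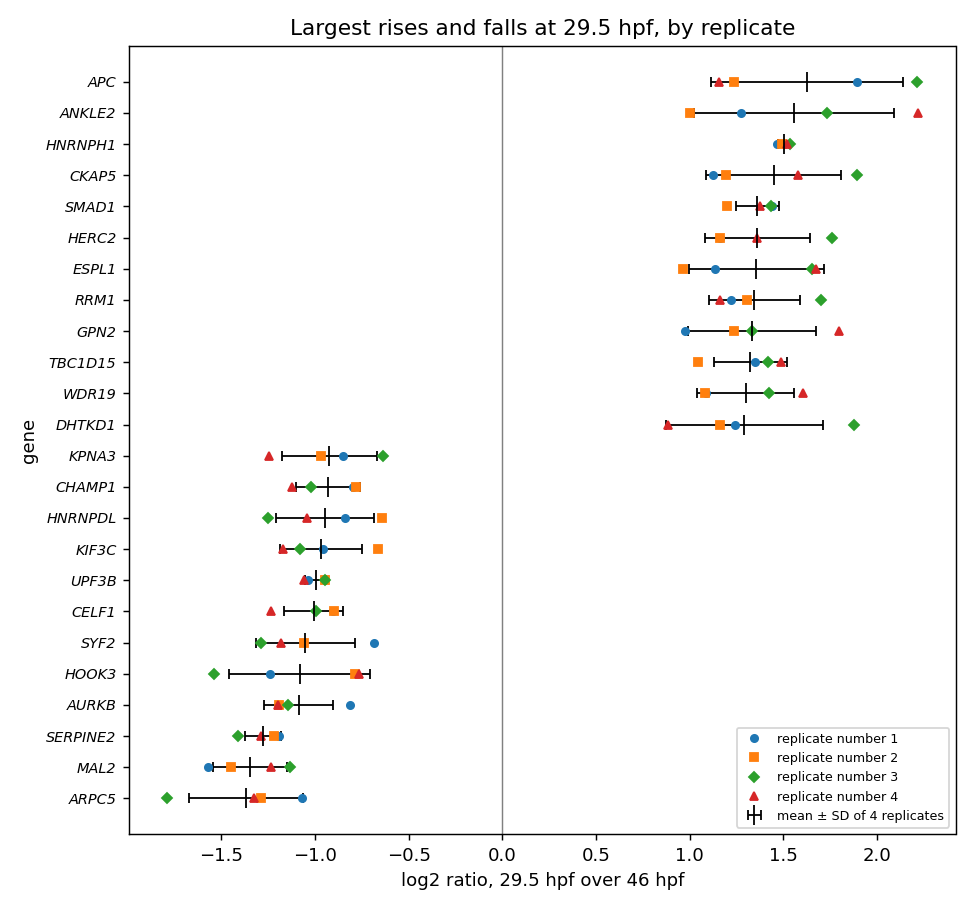
The log2 ratio of 29.5 hpf over 46 hpf (horizontal axis) is plotted for the 12 genes with the largest rises and the 12 with the largest falls (vertical axis); coloured symbols are the 4 labelled replicates, and black ticks with bars are their mean ± SD. All 4 replicates of APC, from 1.16 to 2.21, and all 4 of SERPINE2, from -1.41 to -1.20, lie on one side of 0.

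The counts of probes depended on how the arrays were paired. When replicate numbers 1 and 2 of the arrays with 46 hpf in Cy5 were exchanged, a pairing chosen after seeing the data because the arrays correlated that way, 4 probes were higher and 0 lower by limma, with 4079 probes at an unadjusted p under 0.05 against 5402 in the labelled pairing. The adjusted p of the 382 labelled calls then had a median of 0.106 and a range from 0.0376 to 0.549. Of the 43 called genes named here, 2 passed in the exchanged pairing, HNRNPH1 and SMAD1 (limma adjusted p = 0.0376 for each), and 41 did not. The other probes called in that pairing, looked up after their values were seen, were 1 of CDYL at 1.62, not that gene's brightest, and 1 without a symbol. The SD of HNRNPH1 was then 0.12 and that of SMAD1 0.06, while that of MAL2 went from 0.20 to 0.71, so the SDs given here hold for the labelled pairing. Across probes, the array numbered 1 with 29.5 hpf in Cy5 correlated at 0.67 with the opposite-dye array numbered 2 and at 0.04 with that numbered 1, and probes are not independent replicates. Number 2 of the same orientation correlated at 0.52 with the opposite-dye number 1 and at 0.05 with number 2. Numbers 3 and 4 correlated with their own number at 0.62 and 0.72. Leaving out replicate 1, 2, 3 or 4 ended all calls by limma, with 3977 to 5197 probes at an unadjusted p under 0.05, as did median centring in place of loess, with 6512. The authors' deposited values gave 38 probes higher and 13 lower by limma, so that 74.5% of calls were higher against 54.5%.

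**Figure D2:**
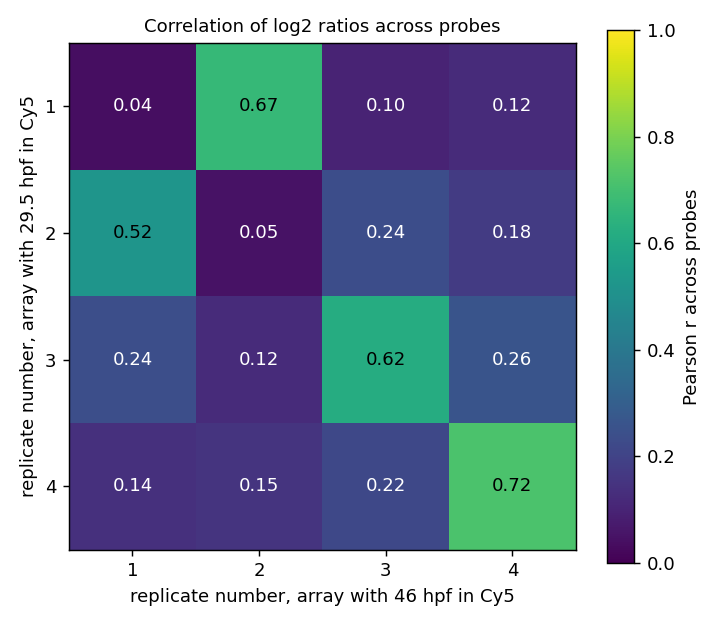
Each cell gives Pearson's r across probes between the log2 ratios of an array with 29.5 hpf in Cy5 (vertical axis, replicate number) and one with 46 hpf in Cy5 (horizontal axis, replicate number). Numbers 3 and 4 are highest on the diagonal, at 0.62 and 0.72, while numbers 1 and 2 are highest off it, at 0.67 and 0.52.

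The called probes had a median log2 ratio of 0.79 among those higher and -0.68 among those lower. By their brightest tested probe 186 genes were called, 114 higher and 72 lower, and 185 of these had 1 sign in all 4 replicates. Genes called only on a probe that was not their brightest are not in this count. Of the called probes, 147 had no gene symbol in the annotation. Of 81 called genes with another tested probe, 59 had the same sign in the brightest other probe and 7 had it called. APC had other probes at 0.03 and 0.11, HNRNPH1 had 1 at -0.04, DHTKD1 had 1 at -0.24, and AURKB had 2 at -0.13 and -0.37, none past the threshold. Other probes of ANKLE2 were at 0.02 and 0.49, that of GPN2 at 0.04, that of WDR19 at 0.10, those of MAL2 at 0.02 and -0.75, and that of UPF3B at -0.10, also not past it. SYF2 had others at -0.86 and -0.67, not past the threshold, CHAMP1 had another called probe at -0.93, and HNRNPDL had a called one at -0.82 and another at -0.26. Within the arrays sharing the number that opens their title, which may mark the slide, the median log2 ratio of the called higher probes was 0.79, 0.79 and 0.81 for 140, 141 and 142, and that of the lower ones was -0.69, -0.67 and -0.66. These probes were chosen on the same arrays.

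Of 25 gene lists fixed before the data were examined, 2 passed limma's camera test with a preset correlation, both toward 29.5 hpf. The DNA repair list had a median log2 ratio of 0.14 over 34 genes (adjusted p = 0.0429) and the spindle and kinetochore list 0.09 over 41 genes (adjusted p = 0.0378). With an estimated correlation both calls were lost (limma camera, adjusted p = 0.541 for each), and fry gave 0.0774 and 0.0529. The estimates were -0.0071 for repair and -0.0039 for spindle, below the preset 0.01. A higher correlation among the members thus did not cost these calls, and the cause of the loss was not examined. In the repair list 2 members rose, 0 fell and 32 did not pass, with 6 higher and 1 lower adjusted over the list alone. MSH6, a mismatch recognition protein, was at 0.95 ± 0.27 (SD, n = 4) and RPA2, a subunit of the single-strand binding complex, at 1.09 ± 0.34 (SD, n = 4), while RPA1 was at -0.31 and PARP1 at 0.54, neither past the threshold. In the spindle list 4 members rose, 1 fell and 36 did not pass, with 10 higher and 3 lower adjusted over the list alone. CENPE, a kinetochore motor, was at 1.22 ± 0.16 (SD, n = 4), ESPL1, the protease separase, at 1.36 ± 0.36 (SD, n = 4), and BUB1B, a spindle checkpoint kinase, at 0.93 ± 0.17 (SD, n = 4), against the fall of AURKB. Both lists passed with numbers 1 and 2 exchanged (adjusted p = 0.0293 for each, limma camera). Neither list passed when replicate 1 or replicate 2 was left out (adjusted p = 0.108 and 0.0787 for both lists, limma camera), or with the strict filter (0.139 for both). The repair median moved from 0.14 to 0.061 without replicate 4 and to 0.092 without replicate 1, and the spindle median moved to 0.051 without replicate 1. Median centring turned the direction: the repair median was then -0.067 (adjusted p = 0.480, limma camera) and the spindle median -0.17 (adjusted p = 0.620), while the median of all genes moved to -0.10 and 0 of the 25 lists had a median above 0. Against that shift the repair list was still higher than the median gene and the spindle list was lower.

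The DNA replication list did not pass (median 0.06 over 42 genes, limma camera adjusted p = 0.052), and 5 of its members rose and 2 fell. RRM1 and POLE2, a subunit of DNA polymerase epsilon at 0.70 ± 0.16 (SD, n = 4), were higher, as was the helicase subunit MCM5 at 0.53 ± 0.09 (SD, n = 4; limma adjusted p = 0.0551 with the replicate block and 0.191 with exchanged numbers), and POLD3 was lower at -0.57 ± 0.11 (SD, n = 4), as was GINS1. Other probes of POLD3 were at -0.29 and -0.22, not past the threshold. With exchanged numbers none of these named members passed (limma adjusted p from 0.0814 for RRM1 to 0.191 for MCM5). Adjusted over the list alone, 10 members were higher and 4 lower. The DNA replication list passed with numbers 1 and 2 exchanged (adjusted p = 0.0358, limma camera) and without replicate 3 (median 0.15, adjusted p = 0.0182). Its median was 0.091 without replicate 2 and 0.11 without replicate 4. In the labelled pairing it had an adjusted p = 0.569 with an estimated correlation (limma camera). In the DNA damage checkpoint list (0.06 over 20 genes, adjusted p = 0.481 by limma camera) 1 member rose, the nuclease MRE11 at 0.83 ± 0.19 (SD, n = 4), with 4 higher and 2 lower adjusted over the list alone. ATR had a log2 ratio of 1.17, CDC25C of -0.56 and RAD50 of 0.33, none past the threshold. No cyclin or cell cycle kinase among 30 passed, and CDK1 was at -0.82, CCNE1 at 0.46, RBL2 at 0.40 and CCNA1 at 0.31. In that list the median was 0.03, the mean -0.01 and the test's direction upward (limma camera, adjusted p = 0.784). In the Wnt list of 27 genes APC alone passed, and CTNNB1, which encodes beta-catenin, was at 0.82 ± 0.30 (SD, n = 4) with a limma adjusted p of 0.0549. That list had a median of -0.02, a mean of 0.03 and a downward test (limma camera, adjusted p = 0.906), with 2 higher and 0 lower adjusted over the list alone. Of 28 growth factor and MAPK signalling genes none passed, with ARAF at -0.40, PDPK1 at -0.47 and MAPK3 at -0.33; the list's median was 0.01, its mean -0.05 and its test downward (limma camera, adjusted p = 0.682).

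**Figure D3:**
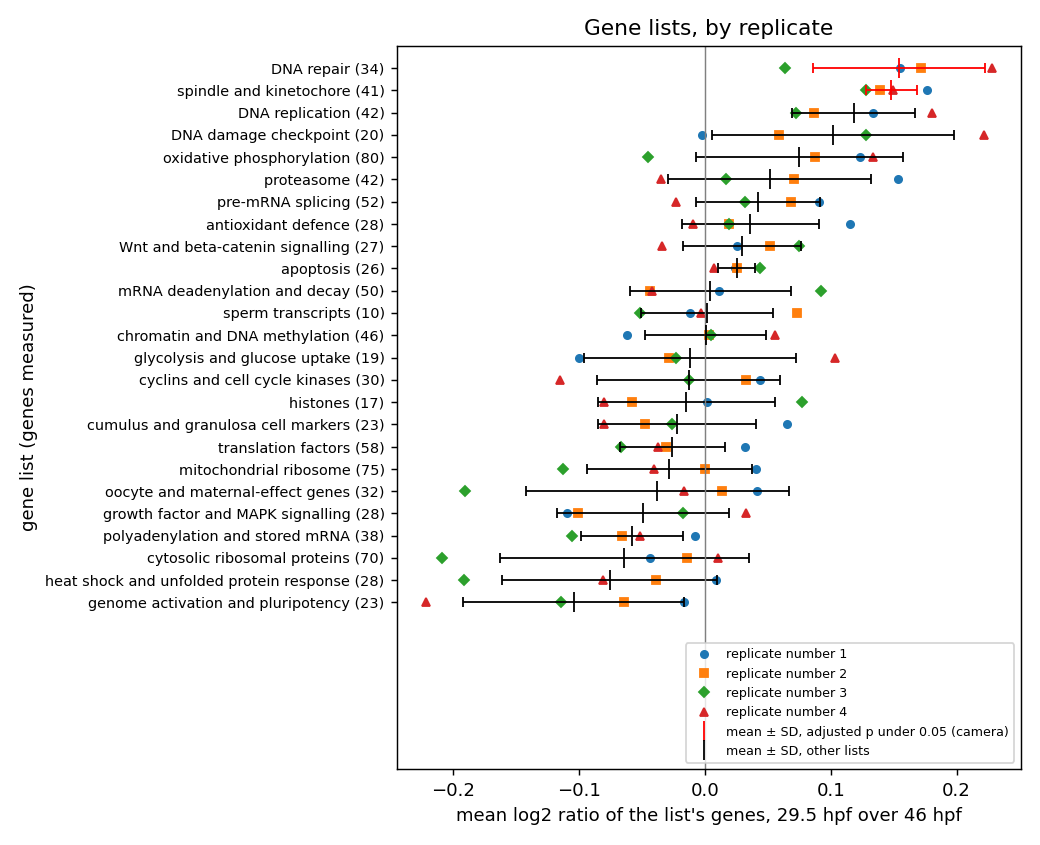
The mean log2 ratio of each list's genes, 29.5 hpf over 46 hpf (horizontal axis), is plotted for 25 lists (vertical axis, with the number of genes measured); symbols are the 4 labelled replicates, ticks with bars are their mean ± SD, and red marks lists past the camera threshold. The DNA repair list, with a mean of 0.15, and the spindle and kinetochore list, also at 0.15, are above 0 in all 4 replicates. So are the DNA replication and apoptosis lists, which did not pass.

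Among 52 pre-mRNA splicing genes 3 rose, PRPF8, the central protein of the spliceosome, at 1.04 ± 0.06 (SD, n = 4), SF3B3 at 0.82 ± 0.22 (SD, n = 4) and HNRNPU at 0.85 ± 0.25 (SD, n = 4), and 0 fell; SRSF1 was at -0.66, not past the threshold. Another probe of HNRNPU was at 0.05, not past the threshold. Among 38 genes of polyadenylation and stored mRNA, CSTF2 rose, at 0.86 ± 0.25 (SD, n = 4), and FIP1L1 fell, at -0.61 ± 0.15 (SD, n = 4), with another probe at -0.06, not past the threshold, while TENT2 at -0.38 and CPEB4 at -0.43 did not pass. Among 50 genes of mRNA deadenylation and decay, UPF3B, a factor of nonsense-mediated decay, fell, with replicates from -1.06 to -0.95, and 49 did not pass, with PAN2 at 1.13, PAN3 at -0.44 and XRN2 at 0.39. None of these lists passed by limma camera, with adjusted p of 0.906 for splicing, 0.571 for polyadenylation and 0.906 for decay, and their medians were -0.01, -0.08 and 0.03. Splicing had a mean of 0.04 and an upward test against its negative median. Adjusted over the list alone, 7 splicing genes were higher and 4 lower, 2 polyadenylation genes were higher and 5 lower, and 2 decay genes were higher and 2 lower. No member passed among 70 cytosolic ribosomal proteins, 58 translation factors and 75 mitochondrial ribosome genes, where RPS10 was at -0.53, EIF4B at -0.44, EEF1A1 at -0.52 and MRPL20 at -0.62. These lists had medians of -0.03, -0.05 and -0.02 (limma camera, adjusted p = 0.571, 0.752 and 0.797), with 0, 0 and 0 members higher and 0, 2 and 0 lower adjusted over the list alone.

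Of 80 oxidative phosphorylation genes 2 rose, NDUFA6 at 0.88 ± 0.24 (SD, n = 4) and NDUFB1 at 0.63 ± 0.16 (SD, n = 4), both subunits of complex I. NDUFB1 did not pass with the replicate block (limma adjusted p = 0.0936) or with exchanged numbers (0.223). NDUFA6 passed with the block (limma adjusted p = 0.0150) and not with exchanged numbers (0.127). The list did not pass (median 0.07, limma camera, adjusted p = 0.0709), with 3 higher and 1 lower adjusted over the list alone. Without replicate 3 the oxidative phosphorylation list passed (median 0.11, limma camera, adjusted p = 0.00917), and over all replicates it had an adjusted p = 0.771 with an estimated correlation (limma camera). ATP5F1B was at 0.76 and NDUFA8 at -0.45, not past the threshold. Of 28 genes of heat shock and the unfolded protein response, the lectin chaperone CANX rose, at 0.59 ± 0.12 (SD, n = 4), and the inducible chaperone HSPA1A fell, at -0.91 ± 0.30 (SD, n = 4). Another probe of HSPA1A was at -0.81 and those of CANX were at -0.34 and 0.27, none past the threshold. That list had a median of -0.08 (limma camera, adjusted p = 0.727), with 2 higher and 1 lower adjusted over the list alone. Of 42 proteasome genes none passed over all probes and 7 were higher and 2 lower adjusted over the list alone, with PSMB6 at 0.87 (another probe at 0.13) and PSMB1 at 0.57 (another at -0.09) (median 0.03, limma camera, adjusted p = 0.571). No member passed among 19 glycolysis genes (SLC2A3 at 0.53), 28 antioxidant genes (CAT at 0.43), 26 apoptosis genes (XIAP at -0.51), 17 histone genes (SLBP at -0.26) and 46 chromatin genes (KDM3A at 1.61). Their medians were -0.04, 0.04, 0.03, -0.03 and -0.04 (limma camera, adjusted p = 0.906, 0.682, 0.906, 0.906 and 0.906), and the chromatin list's mean was above 0 by under 0.01. Adjusted over the list alone, 4 chromatin genes were higher and 6 lower, 1 apoptosis gene was lower, and 0 passed in the other lists of that group.

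Among 32 oocyte and maternal-effect genes NLRP2 rose, at 0.61 ± 0.05 (SD, n = 4), and PADI6 was at -0.52, LHX8 at -0.64 and DDX4 at 0.47, not past the threshold (list median -0.07, limma camera, adjusted p = 0.752; 1 higher and 0 lower adjusted over the list alone). Among 23 genes of genome activation and pluripotency SALL4 fell, at -0.50 ± 0.10 (SD, n = 4). This call was lost with the replicate block (limma adjusted p = 0.177) and with exchanged numbers (0.336), where its SD was 0.43. The NLRP2 call was kept with the block (limma adjusted p = 0.0189) and lost with exchanged numbers (0.1245). NFYC was at -0.41 and GTF2B at 0.30, not past the threshold (list median -0.07, limma camera, adjusted p = 0.571; 1 higher and 2 lower adjusted over the list alone). The markers of other cells that such samples can hold did not pass as lists by limma camera. The 23 cumulus and granulosa cell markers had a median of 0.00, a mean of -0.02 and an upward test (adjusted p = 0.959). SERPINE2 was the 1 member that fell, also adjusted over the list alone. The 10 sperm transcripts had a median of -0.05, a mean of 0.00 and a downward test (adjusted p = 0.959), with 1 higher and 0 lower adjusted over the list alone.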

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

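The tests on the numbering of the arrays, on the opening numbers of the titles and on SERPINE2 were chosen only after the result was seen, as were the separate brightness test of each list and its allowance for the error of the draw; those on the dye of the gene lists and on the turned signs were not. A replicate or array far from the other 3 of its group was found in 6 of 162 groups of 4 values examined, and chance gives about 1 in 20. The gap of the outlying value to its nearest neighbour was 0.855 of the range for AURKB (replicate 1 at -0.81, the others from -1.20 to -1.14), 0.913 for MAPK3 (replicate 3 at -0.56), 0.879 for MRPS9 (replicate 4 at -0.42), 0.864 for SLC2A3 (replicate 4 at 1.24, the others from 0.22 to 0.36) and 0.931 for PDK1 (replicate 2 at -0.54). The median Cy3 background was 48 on the array numbered 2 with 46 hpf in Cy5 and 21 to 22 on the other 3 of that orientation, a gap of 0.963 of the range. Of the 8 patterns of turned signs of the replicate means, 1, the real one, called 382 probes and the highest of the others called 0, and 8 splits are too few for a share under 0.05.

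The first pattern is that 382 probes were called with the arrays averaged by number and 4 with numbers 1 and 2 exchanged. A shared opening number is argued against for 1 crossed pair, since the array numbered 1 with 29.5 hpf in Cy5 correlated more by 0.631 with the opposite-dye number 2, of another opening number, than with number 1, of the same one. The other crossed pair correlated at 0.52 and shares its opening number, but the other 6 pairs of arrays that share one had a median correlation of 0.219 and a range from 0.04 to 0.36, which argues against it there too. An exchange of the numbers between dye orientations is a candidate explanation: the lower crossed correlation was above the higher own-number one by 0.473, and numbers 3 and 4 paired with their own number. If so, the labelled means numbered 1 and 2 would each average the same 2 biological replicates and would not be independent of each other. The spread between the 4 means would then tend to be too small. The n of 4 given with each SD counts labelled replicates. Simulated wrong pairs without any change gave 8.23% of probes at unadjusted p under 0.05 (limma) and true pairs 5.43%. Neither gave a call after adjustment. Those runs held no changed probes and drew each probe independently. They cannot show how wrong pairs alter the number of calls where changes are present, so they do not bear on the 382 calls.

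The second pattern is that the DNA repair and the spindle and kinetochore lists were higher at 29.5 hpf. Dye bias left after normalization is argued against, because the lowest of the medians of the lists over both dye orientations was 0.106. A dye effect of like size in both orientations also cancels in each pair mean by design, so this check adds little to the calls. The 10000 random lists matched on intensity had a median of -0.00787 for the repair list and -0.00576 for the spindle list. Genes of like brightness thus did not rise as a whole. Among these lists the repair median was at percentile 99.96, which argues against brightness for that list. The spindle median was at 97.7 (SE 0.150), too near the bound (0.0888 against 0.0876) to tell it from the spread of the random lists. A chance draw of genes of like brightness stays open for the spindle list. The normalization stays open too, since with median centring in place of loess the medians were -0.067 for the DNA repair list and -0.17 for the spindle and kinetochore list, and that of all genes was -0.10. The difference between early and late cleaving embryos that the design names stays open and untested apart from these checks, and both calls were lost with an estimated correlation. The estimates themselves, -0.0071 for repair and -0.0039 for spindle, were below the preset 0.01.

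The third pattern is the lower SERPINE2 signal at 29.5 hpf. More cumulus cell RNA in the 46 hpf samples was examined through the 6 other members of the cumulus list brighter than the median gene. They had a median of 0.0358 (SE 0.160), against a bound of -0.64 set from the SERPINE2 change. The brightest, STAR, was at 0.67 (other probes at 0.16 and -0.02), PTGS2 at 0.38 and GJA1 at 0.23. HAS2 was at -0.29, INHBA at -0.27 and KRT8 at -0.16. None fell to the bound, which argues against cumulus RNA only as far as these genes report cumulus cells. The other 16 members were dimmer, where a change would show less. How many of these genes the embryos express themselves was not tested, so cumulus RNA is not excluded. Per the labels the zygotes had been stripped of cumulus mechanically. Whether the change belongs to 1 probe alone cannot be told apart from a change of the transcript, since 0 other probes of SERPINE2 were tested.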

How the results depend on the processing

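The exchanged numbering, the fits with it, the use of replicates 3 and 4 alone and the threshold of 0.1 were chosen after seeing the data. Of the 43 called named genes, 2 stayed called with numbers 1 and 2 exchanged (HNRNPH1 and SMAD1), 13 with the authors' values, 15 with a trended, robust prior, 40 with the replicate block under either numbering and 0 with median centring or without any 1 replicate. None of them changed sign in the alternatives run, but both called lists did with median centring: the DNA repair list had a median of -0.067 against 0.14 and the spindle and kinetochore list -0.17 against 0.09, while the median of all genes moved to -0.10. Except where stated the cause was not tested. The counts of probes higher at 29.5 hpf and probes lower at 29.5 hpf, 208 and 174, became 345 and 271 without background correction, 458 and 405 with the strict filter, which tests fewer probes, 38 and 13 with the authors' values, 27 and 10 with a trended, robust prior, 991 and 1228 with array weights, 1621 and 1797 with the title's opening number as a random block, 937 and 943 with 8 arrays as independent, and 697 and 707 at an adjusted p under 0.1. They were 0 and 0 by limma with median centring (6512 probes at unadjusted p under 0.05), with only the arrays with 29.5 hpf in Cy5 (3564) or only those with 46 hpf in Cy5 (4815), with only replicates 3 and 4 (4042), and without replicate 1, 2, 3 or 4 (from 0 to 0 in each direction; 3977 to 5197 at unadjusted p under 0.05), where fewer replicates enter.

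By pairing, the replicate block by the labelled numbers gave 568 and 560 (correlation within a number 0.209) and the block by the exchanged numbers 383 and 359 (0.484), while exchanged pair means gave 4 and 0. The block by the title's opening number had a negative correlation, -0.142, which makes the error of a mean smaller than with independent arrays. The fit with independent arrays left out the correlation within a number and took dye-swapped arrays of one replicate as separate samples. The higher counts from these fits are thus not evidence of more changed probes. Array correlations were highest with the own number for numbers 3 and 4 and not for 1 and 2. Counts of probes higher at 29.5 hpf and probes lower at 29.5 hpf within 1.5 times those came from normexp with an offset of 16 (167 and 130), no filter (169 and 159), a fold of at least 1.5 (174 and 127) and Aquantile, which leaves the ratios as they are by construction.

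The number of lists past the threshold, 2 with the chosen settings, was 6 with median centring, none of them repair or spindle, 0 with the strict filter, 4 with the authors' values, 4 with the replicate block, 4 with the block by exchanged numbers, 4 with independent arrays, 4 with the title block, 0 with only 46 hpf in Cy5, 0 with only replicates 3 and 4, 0 with an estimated correlation and 0 with fry, and from 0 to 4 when a replicate was left out. With numbers 1 and 2 exchanged 3 lists passed, as did 3 with array weights. Repair and spindle were among them in each (limma camera, adjusted p = 0.0293 for both with exchanged numbers and 0.00532 for both with array weights). By fry's mixed test, which asks whether any members differ in either direction, 20 of the 25 lists passed. Over all tested probes 16.38% had an unadjusted p under 0.05 by limma. Random lists were not put through the mixed test, so the 20 is not particular to these lists as far as was examined. Signal over background limits the dim probes: a different filter moved the probes tested from 18234 to 43788.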

Other observations

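The tests on 2 further gene lists were set before their result was seen, and that on the probes of one gene after. Among the genes called higher at 29.5 hpf were 4 of ribosome assembly, UTP15 at 1.21, UTP6 at 0.78, NOP58 at 0.69 and MDN1 at 0.46, and 4 of the centrosome and microtubule nucleation, CKAP5 at 1.45, TUBGCP4 at 1.21, CETN3 at 0.85 and CEP120 at 0.64, and these were chosen after their values were seen. A hypothesis that each group moved as a set was tested on the remaining members, without any called gene. The other 72 ribosome assembly genes had a median of -0.03 and the other 49 centrosome genes -0.04, with an adjusted p of 0.648 for each by limma camera. No shift toward 29.5 hpf was found in the remaining members, and a shift of either whole group is not excluded, since its called genes were left out.

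A hypothesis that the probes of one gene share its change was tested in the 81 called genes with another tested probe. The brightest other probe had the same sign in 72.8% of them, and its log2 ratio was a median of 0.168 of that of the called probe. The other probe was dimmer than the called one in every gene, by the rule that chose the probes, and a change would show less there. A called probe may also report a transcript form or end that the other probe does not, or a chance extreme of the chosen probe. These were not told apart, and probe sequences were not used here.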
